A study of Mus musculus with 9 samples.

How the data were processed

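Total RNA of whole lungs was amplified in 2 rounds and hybridised to Agilent arrays of 2 colours, per the labels' protocols, with pooled RNA of the PBS-treated lungs in Cy3 and the RNA of the sample in Cy5. Samples were grouped by the channel 2 source in the labels into PBS (4 arrays) and OVA (5 arrays), and each table column was matched to its sample by name. The arrays were read with Agilent Feature Extraction 8.5.1.1, per the submitters' processing notes. The authors' background correction, dye normalization and error model are not given in the sources used here.

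The deposited table holds for each of 39464 probes and each array an intensity in channel 1, an intensity in channel 2 and a p-value, per the file headers. The intensity values were already scaled by the authors, by a method not given in the sources used here, and the totals of single channels lay between 41722 and 43610. The file headers number the channels and do not name the dyes, so channel 2 was taken as Cy5 from the labels. The deposited p-value of each probe and array was used only to count probes. A second deposited table holds log10 ratios for 39462 of the probes. They equalled the log10 of channel 2 over channel 1 (correlation of 1 on each array, with 99% of differences under 0.00044 in size). The median of each of its columns was 0, and its scale and direction are known only from this match. There were 0 columns of other samples.

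Cells were blank for 138 probes on at least 1 array. Where these probes had a value, their median intensity was 33.2, against 0.14 over all probes. For 30 probes all 4 PBS arrays were blank, and 41 genes had too few values for a test. The intensities are rounded, and between 27.7% and 48.8% of probes had a ratio of exactly 1 on an array. No background, saturation flag, slide or scan date was used.

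Probe names were updated with a RefSeq gene table of the assembly GRCm38.p6, used for names only. For 22966 probes the symbol was current, for 3130 it was a synonym of 1 gene, 4009 kept the symbol of the file and 11 were named through their accession. No name was given to 9317 probes and to 31 whose symbol had been turned into a date. Each gene was represented by the probe with the highest mean intensity, which left 25756 genes, of which 25715 had at least 2 values in each group.

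Log2 ratios of channel 2 over channel 1 were compared between OVA and PBS arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over all genes tested, adjusted p under 0.05, no covariates). Changes are log2 differences with the moderated standard error. The 38 gene lists were compared with camera (preset correlation 0.01, two-sided, Benjamini-Hochberg over lists with at least 3 members), and beside it with an estimated correlation, with fry, and with counts of members past the threshold over all genes and adjusted over the list alone. The lists held 1022 entries, 974 of them on the array, and 48 genes stood in more than 1 list. In 2 cases, Clc and Rmcs1, an entry matched an unrelated gene and was left out. Lists of cell types are read as levels of those genes in whole-lung RNA. Both steps were tested on simulated ratios for 25715 genes, with 200 of them changed between OVA and PBS. Of changes of 0.5, 1 and 2 on the log2 scale, 76.1%, 91.0% and 100% were recovered, and 5.82% of calls were false. Of 200 lists of unchanged genes, 1% had an unadjusted p under 0.05. The simulated genes were independent of each other. These shares therefore do not cover lists of correlated genes, nor as many changed genes as were called in the data.

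The genes to name, the lists, the tests and most alternatives were fixed before the data were examined. Named were the 8 largest rises and the 8 largest falls among genes past the threshold whose OVA arrays all lay on 1 side of the PBS arrays, up to 3 members of each list with the largest change past the threshold (or the smallest p in a list with none past it), and 22 genes long linked to the ovalbumin model whatever their result. Members of lists given only as counts were left out, and 1 gene that the rule names is not reported here. Genes named for the levels of single channels or of carried-over tissue were chosen after their values were seen.

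The alternatives were the second table, quantile normalised or median-centred ratios, loess within arrays (span 0.3), 50 added to both channels, channel 2 alone, a filter on the dimmest 0.25 of probes, the mean over a gene's probes, each probe as its own test, the replicate number as a block, each array left out, array weights, a trended and robust prior, an unmoderated unequal-variance test per gene, stricter thresholds and other list tests. Chosen after seeing the data were the OVA arrays alone against 0, 0.05 added to both channels, channel 1 alone, and the ratios of the OVA arrays turned in sign. Each count was also computed for 100 splits of the 9 arrays into 4 and 5. The intensities of both channels were quantile normalised together before channels were compared with each other.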

Results

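Whole-lung RNA of BALB/c mice was profiled on 9 Agilent arrays of 2 colours. The mice were about 12 weeks old. They had been challenged with ovalbumin (OVA, the allergen of a widely used mouse model of allergic airway inflammation) or treated with saline (PBS). By the labels, 4 arrays carried PBS-treated lungs and 5 carried OVA-challenged lungs. Also by the labels, each array held the RNA of 1 lung in the Cy5 channel (channel 2) and a pool of the PBS-treated lungs in the Cy3 channel (channel 1). Between 39376 and 39451 probes had a value on each array, and the median intensity of an array lay between 0.12 and 0.17 on the deposited scale, which ran from 0.00055 to 70.2. The number of arrays limits the precision, and the labels do not say that each lung came from its own mouse, so the p-values measure the spread between these samples.

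The comparison asked which genes differ between OVA-challenged and PBS-treated lungs. In the deposited ratio of channel 2 over channel 1, mucus, macrophage, chemokine and cell division genes were higher on the arrays labelled OVA, and genes of alveolar type 1 cells, endothelium and xenobiotic metabolism were lower. With an estimated correlation between genes, the alveolar type 1 and endothelial list calls were lost (adjusted p = 0.077 and 0.15). Clca1 (listed as Clca3), a protein secreted by goblet cells, was 103-fold higher (log2 change 6.69 ± 0.16 SE, n = 5 against 4, adjusted p = 8.17e-08). Fabp1, a fatty acid binding protein, was the gene with the largest fall (log2 change -4.21 ± 0.09 SE, adjusted p = 6.03e-08). All directions given here are those of the deposited ratio, and the single channels go against the labels: the RNA with high Clca1 was in both channels of the arrays labelled PBS and in channel 2 of the arrays labelled OVA. If channel 1 of the OVA arrays holds the OVA-labelled lungs, higher and lower are exchanged for nearly all of the changes. With the ratios of the OVA arrays turned in sign, 9063 of the 9077 genes called both ways had the opposite sign. Since the PBS ratios lie near 0, this count follows from the turn itself and is no test. If the group names are exchanged as well, the deposited directions are those of challenged over PBS-treated lungs. Which of these cases holds cannot be told.

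Of 25715 genes tested with limma, 10364 changed at an adjusted p under 0.05, 4454 higher and 5910 lower, and 782 of these changed at least 2-fold, 632 higher and 150 lower. Quantile normalised ratios gave 4528 genes, 2180 higher and 2348 lower, and 447 changed at least 2-fold, 360 higher and 87 lower. With the ratios of the OVA arrays turned in sign, 10037 genes changed, 5784 higher and 4253 lower, and 788 of them at least 2-fold, 162 higher and 626 lower. The 5 OVA arrays all lay on 1 side of the 4 PBS arrays for 8881 genes (34.5%), against 1.59% by chance. The log ratios of the OVA arrays correlated with each other across genes at r between 0.889 and 0.966, where genes are not independent replicates. Those of the PBS arrays correlated with each other at r between -0.534 and 0.374, as ratios of single lungs to a pool of the same lungs.

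**Figure D1:**
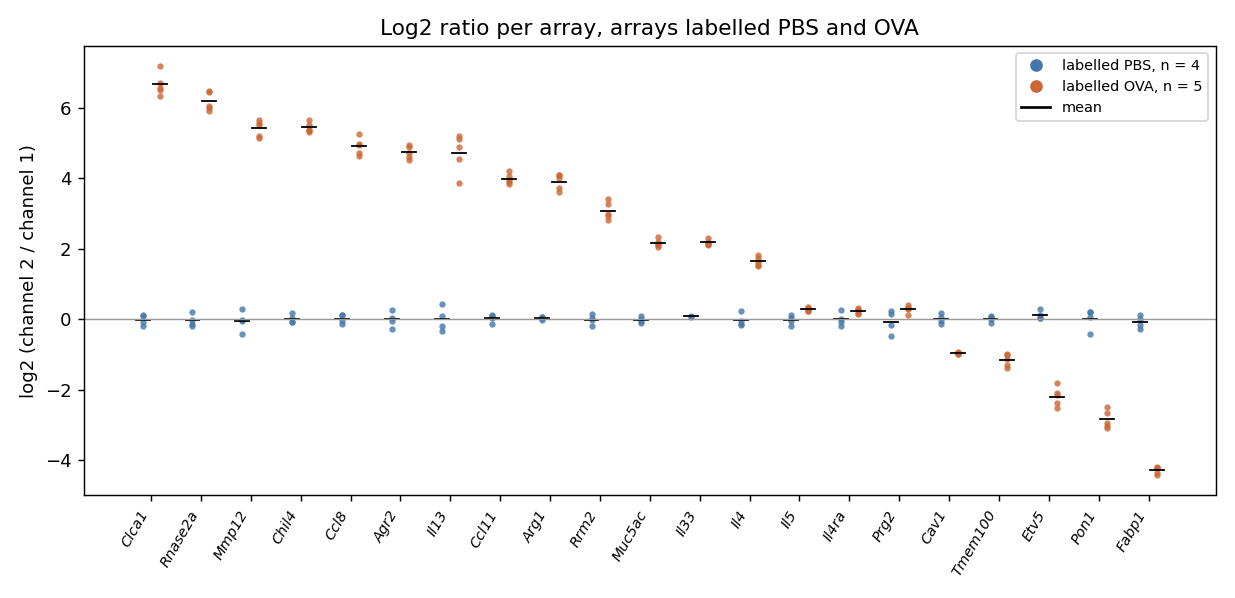
Log2 ratio of channel 2 over channel 1 (vertical axis) for named genes (horizontal axis), 1 point per array, blue for the 4 arrays labelled PBS and orange for the 5 labelled OVA, with black bars for means. The PBS arrays lie near 0 for each gene, while the OVA arrays reach a mean of 6.67 for Clca1 and -4.29 for Fabp1.

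Other large rises among named genes were those of Slc26a4, an anion exchanger (about 79.2-fold, with values on only 2 PBS arrays), and Rnase2a, an eosinophil-associated ribonuclease listed as Ear11 (74.6-fold). Among them were also a probe listed as V1rg6 and now Vmn1r75, a vomeronasal receptor (55.7-fold), and Mmp12, the macrophage elastase (44.6-fold). Large rises were also seen for Chil4 (listed as Chi3l4), a chitinase-like protein (43.2-fold), Retnlb, a resistin-like molecule (31.8-fold), and the chemokine Ccl8 (29.8-fold). The fold of Slc26a4 is not exact, since its channel 2 averaged 55.1 on the OVA arrays, toward the top of the deposited scale. For these 7 genes the adjusted p lay between 2.58e-08 for Chil4 and 7.73e-06 for Slc26a4. Other large falls were those of Pon1, paraoxonase (log2 change -2.86 ± 0.17 SE), the transcription factor Etv5 (-2.32 ± 0.14) and Esm1, an endothelial proteoglycan (-2.23 ± 0.19). Asgr1, a subunit of the asialoglycoprotein receptor (-2.19 ± 0.17), fell as well, as did the cytochromes Cyp2a4 (-2.17 ± 0.30) and Cyp2a5 (-2.09 ± 0.31), near-identical copies that probes may not tell apart. Second probes had a smaller log2 change for Clca1 (0.31), Pon1 (-0.88) and Cyp2a5 (as small as -0.81 among 3 probes), and that of Cyp2a4 went in the other direction (0.035).

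Of 22 measured type 2 cytokine and receptor genes, 12 rose, 2 fell and 8 did not pass the test, with 14 up and 2 down when adjusted over the list alone. Il13, the cytokine that drives mucus production, was 26.5-fold higher (log2 change 4.73 ± 0.29 SE, adjusted p = 5.67e-06), and Il21 was 16.5-fold higher (a second probe at a log2 change of 0.35). The alarmin Il33 was about 4.29-fold higher (values on 2 PBS arrays, and a channel 2 of 49.3 on the OVA arrays, so not exact), Il4 3.19-fold, the decoy receptor Il13ra2 1.71-fold and the eosinophil growth factor Il5 1.24-fold (adjusted p = 0.0037). For Il5 the call was lost with quantile normalised ratios (adjusted p = 0.23, and from 0.00064 to 0.23 over the alternatives other than channel 2 alone). Il4ra, the receptor chain shared by Il4 and Il13, had a log2 change of 0.24 ± 0.09 SE (adjusted p = 0.057; 0.0030 without PBS replicate 3). The list as a whole was shifted upward (camera, adjusted p = 1.96e-04), a call lost with an estimated correlation (adjusted p = 0.062).

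All 22 tested genes of alternatively activated macrophages rose, with a median log2 change of 1.91 (camera, adjusted p = 8.42e-22; with an estimated correlation, adjusted p = 0.033; 22 also when adjusted over the list alone). Beside Mmp12 and Chil4 they included Arg1, arginase, at 14.7-fold, Chia1 (listed as Chia), the acidic mammalian chitinase, at 7.33-fold, and the eosinophil-attracting chemokine Ccl24 at 3.82-fold. Chil3 (listed as Chi3l3) and Retnla, both secreted by such macrophages, had blank cells on all 4 PBS arrays and were not tested between groups. On the OVA arrays their channel 2 was 15.2-fold and 8.70-fold above channel 1 (log2 ratio 3.92 ± 0.26 and 3.12 ± 0.50, SD, n = 5). Their channel 2 averaged 61.3 and 61.7, near the highest deposited intensity of 70.2, so these ratios are not exact.

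Among goblet cell and mucus genes, 18 of 22 rose and 2 fell, the same numbers when adjusted over the list alone, with a median log2 change of 2.25 (adjusted p = 7.62e-14; with an estimated correlation, adjusted p = 0.033). Agr2, a chaperone for mucins, had a log2 change of 4.75 ± 0.12 SE. The lectin Itln1 was 27.3-fold higher (a second probe at a log2 change of 1.42), the goblet cell transcription factor Spdef 5.02-fold and the mucin Muc5ac 4.53-fold. Chemokines rose in 24 of 32 cases and fell in 3, also when adjusted over the list alone (median 1.53, adjusted p = 9.06e-12; with an estimated correlation, adjusted p = 0.033). Among them were Ccl11 (eotaxin) at 15.6-fold, Ccl17 at 4.48-fold and the neutrophil attractant Cxcl3 at a log2 change of 4.00 ± 0.22 SE.

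All 42 cell division genes rose, also when adjusted over the list alone (median log2 change 1.97, adjusted p = 5.44e-36; with an estimated correlation, adjusted p = 0.033). Pbk, a mitotic kinase, was 8.68-fold higher. Rrm2, a ribonucleotide reductase subunit, was 8.56-fold higher (a second probe at a log2 change of 0.29) and the kinesin Cenpe 7.93-fold. Of 22 complement and acute phase genes, 14 rose and none fell, or 15 and none when adjusted over the list alone (median 1.17, adjusted p = 8.68e-10; with an estimated correlation, adjusted p = 0.033). Saa3 and Saa1, serum amyloid proteins, were 15.3-fold and 7.19-fold higher and C1qc, a chain of complement C1q, 7.08-fold.

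Of 15 eosinophil genes, 9 rose and 2 fell, or 11 and 2 when adjusted over the list alone (median log2 change 0.48, adjusted p = 1.36e-05; with an estimated correlation, adjusted p = 0.077). The ribonucleases Ear3, Ear2 and Ear12 were 5.14-fold, 3.89-fold and 3.73-fold higher, but these are near-identical copies. Prg2, the major basic protein of eosinophil granules, had a log2 change of 0.37 ± 0.14 SE (adjusted p = 0.072; 0.032 without PBS replicate 2). Of 27 dendritic cell and MHC class II genes, 21 rose and 1 fell, also when adjusted over the list alone (median 0.82, adjusted p = 2.70e-10; with an estimated correlation, adjusted p = 0.077). The transcription factor Batf3 and the integrin Itgax were each 6.66-fold higher, and the monocyte chemokine receptor Ccr2 3.64-fold.

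Among genes of the lung's own cells, 19 of 21 alveolar type 1 genes fell and 2 rose, also when adjusted over the list alone (median log2 change -0.54, adjusted p = 1.01e-06; with an estimated correlation, adjusted p = 0.077). Emp2, a membrane protein, was at -1.22 ± 0.23 SE and the caveolins Cav2 and Cav1 at -1.10 ± 0.08 and -0.98 ± 0.06. Endothelial genes fell in 25 of 36 cases and rose in 5, or 26 and 5 when adjusted over the list alone (median -0.51, adjusted p = 3.05e-05; with an estimated correlation, adjusted p = 0.15). Tmem100 was at -1.17 ± 0.09 SE and the VEGF receptor Kdr at -1.04 ± 0.12. Sele, E-selectin of activated endothelium, was 11.7-fold higher (a second probe at a log2 change of 0.033). Club cell genes fell in 14 of 21 cases and rose in 2, or 15 and 2 when adjusted over the list alone (median -0.48, adjusted p = 7.76e-04; with an estimated correlation, adjusted p = 0.26). Scgb1a1 was not analysed here, since no probe was matched to it.

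Of 36 xenobiotic metabolism genes, 25 fell and 5 rose, also when adjusted over the list alone (median log2 change -0.39, adjusted p = 3.05e-05; with an estimated correlation, adjusted p = 0.033). Among them were the sulfotransferase Sult1d1 at -1.66 ± 0.14 SE and Cyp2a5. Of 22 alveolar type 2 genes on the array, 18 were tested and 15, with a value on each array, entered the list test. Blank cells lay mostly on bright probes, so the brightest members may be missing. Of the 18, 7 rose and 8 fell, or 8 and 8 when adjusted over the list alone, and the list was not shifted (median 0.0017, adjusted p = 0.84). Its antibacterial member Lyz2 was at -1.03 ± 0.11 SE. Ciliated cell genes rose in 6 and fell in 10 of 29 cases, or 8 and 10 when adjusted over the list alone (median -0.083, adjusted p = 0.40), with Tppp3, a tubulin-binding protein, at -0.99 ± 0.11 SE.

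**Figure D2:**
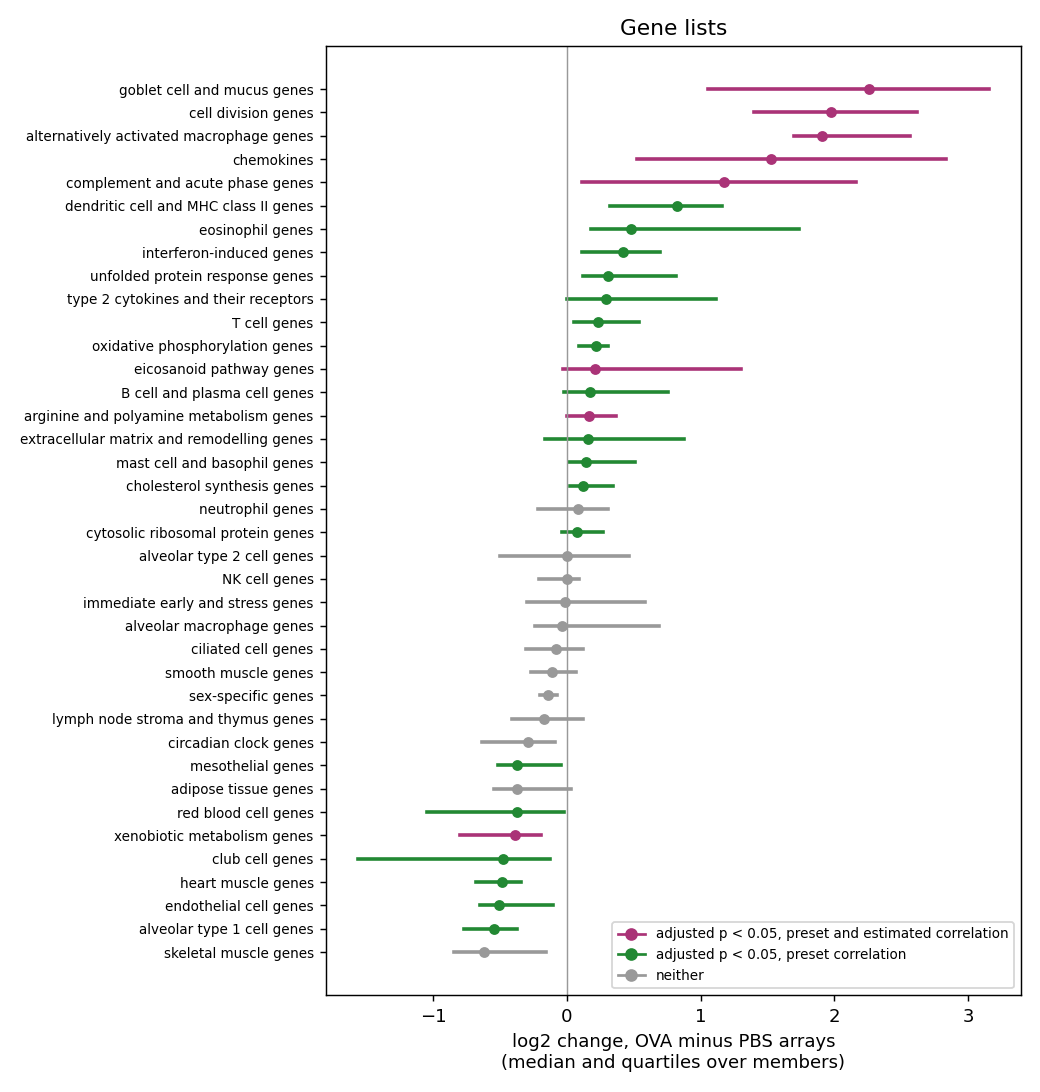
Median log2 change between the arrays labelled OVA and PBS (point, horizontal axis) with the quartiles over members (line) for the 38 fixed gene lists (vertical axis), coloured by whether the list test passed with the preset and with the estimated correlation. The goblet cell list has the highest median, 2.25, and the alveolar type 1 list lies at -0.54.

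The intensities of the single channels were set side by side. Clca1 was at 33.6 ± 1.20 in channel 1 and 33.3 ± 3.84 in channel 2 of the PBS arrays (SD, n = 4), and at 36.4 ± 2.03 in channel 2 and 0.362 ± 0.0642 in channel 1 of the OVA arrays (SD, n = 5). Fabp1 was at 0.11 ± 0.005 and 0.10 ± 0.015 on the PBS arrays, and at 0.126 ± 0.0152 in channel 2 and 2.47 ± 0.318 in channel 1 of the OVA arrays. Channel 2 alone gave no gene that differed between the OVA and PBS arrays (0 of 25715 with limma, 1638 at an unadjusted p under 0.05), although by the labels it holds the lungs compared. Channel 1 alone, by the labels the same pool on each array, gave 8078 genes, and of the 7023 that the ratio also called, 7017 had the opposite sign.

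**Figure D3:**
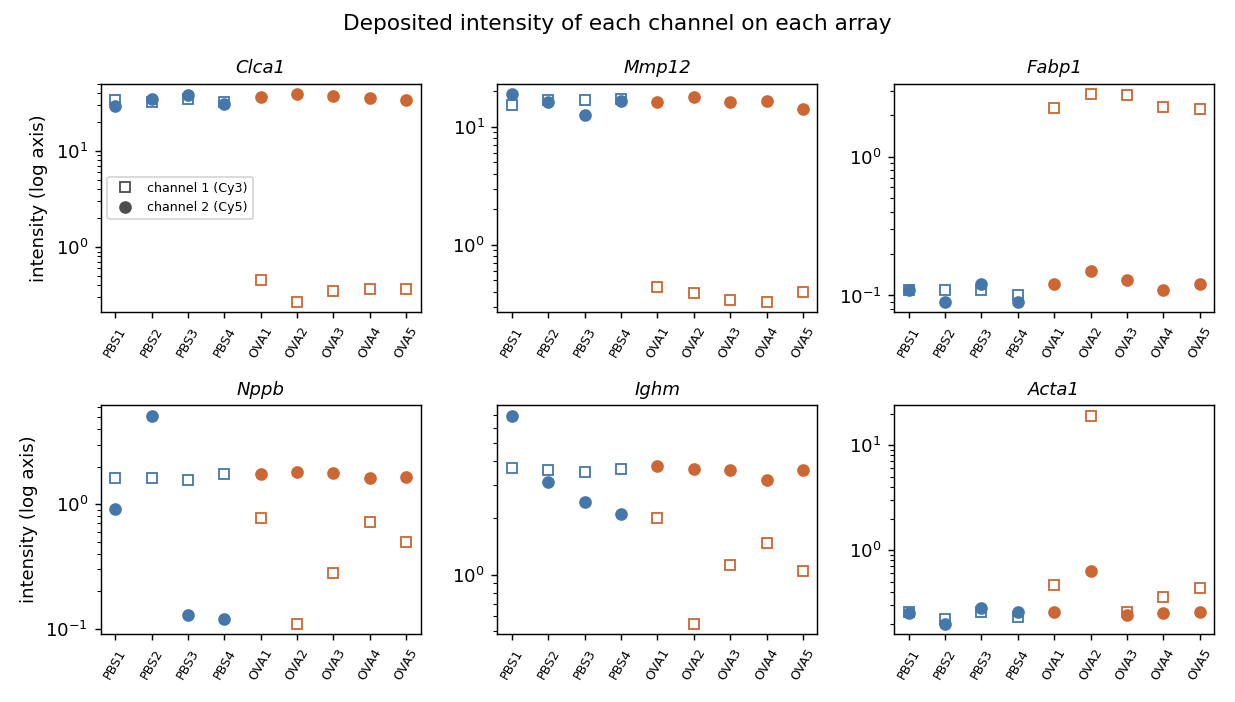
Deposited intensity (vertical log axis) of 6 genes on each of the 9 arrays (horizontal axis), open squares for channel 1 and filled circles for channel 2, blue for arrays labelled PBS and orange for those labelled OVA. Clca1 is near 33.6 in channel 1 of the PBS arrays and near 0.362 in channel 1 of the OVA arrays, and Nppb is even in channel 1 of the PBS arrays and in channel 2 of the OVA arrays.

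Nppb, a natriuretic peptide of heart muscle, was at 1.64 ± 0.0733 in channel 1 and at 1.57 ± 2.39 in channel 2 of the PBS arrays (SD, n = 4). On the OVA arrays it was at 1.72 ± 0.0798 in channel 2 and at 0.476 ± 0.282 in channel 1 (SD, n = 5). Over the 100 genes that varied most in channel 2 between the PBS arrays, the median SD of log2 intensity on the OVA arrays was 0.42 in channel 1 and 0.14 in channel 2. Heart muscle genes as a list fell (median log2 change -0.49, adjusted p = 0.034; with an estimated correlation, adjusted p = 0.66), with 1 of 24 up and 7 down, also when adjusted over the list alone. Their medians ranged from -0.69 to 0.59 between the PBS arrays. The list call was lost without PBS replicate 1 (adjusted p = 0.082), PBS replicate 2 (0.18), OVA replicate 1 (0.062) or OVA replicate 4 (0.062), and without the dimmest 0.25 of probes (0.054). Nppb itself was higher in the ratio (log2 change 3.81 ± 1.20 SE, adjusted p = 0.035), with overlapping groups. Its call was lost without PBS replicate 1, 3 or 4 or OVA replicate 2, 3, 4 or 5 (adjusted p from 0.051 to 0.098). Skeletal muscle genes had a median log2 ratio of -2.57 on OVA replicate 2 and adipose tissue genes of -1.27 on OVA replicate 4.

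With the preset correlation, other splits of the 9 arrays gave up to 29 shifted lists against 26 for the labelled groups, so the number of such lists is no measure of the difference. Folds of genes with a dim channel are not exact, since intensities carry few decimals: for 12 named genes whose dimmer channel averaged at most 0.078 on the OVA arrays, 0.05 added to both channels lowered the fold by over 1.5 times. This also changes the order of the largest rises. The log2 change was then 5.46 for Rnase2a, 3.74 for Retnlb, -1.51 for Asgr1, 3.79 for Il13, 2.38 for Il21, 1.33 for Ccl24, 2.90 for Cxcl3, 2.39 for Pbk and 2.76 for Sele.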

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

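The tests of channel 1 alone, of the spread and level of single channels, of the splits and of the alveolar type 1 against the ciliated list were chosen only after the result was seen.

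The first pattern is that the arrays labelled OVA owe their ratios to channel 1. A difference between the sets of arrays that reaches both channels is argued against: channel 2 alone gave 0 genes and channel 1 alone 8078, against 10364 by the ratio. Over 12776 bright genes, channel 2 of the OVA arrays lay close to channel 1 of the PBS arrays on average. The SD of the log2 difference was 0.118, with 2 genes at least 2-fold apart. For channel 1 of the OVA arrays these were 0.557 and 673, which argues against the same pool in channel 1 of all arrays. Of 100 genes that varied between the lungs on the PBS arrays, 73 spread more in channel 1 than in channel 2 of the OVA arrays (median SD of log2 intensity 0.42 against 0.14). So did 66.8% of all bright genes (0.136 against 0.104). Over all bright genes the median SD on the PBS arrays was 0.0712 in channel 1 and 0.106 in channel 2. There, channel 2 of the OVA arrays spread like the channel of the single PBS lungs, which limits the reading as a pool. On the 100 genes its 0.14 was nearer to channel 1 of the PBS arrays (0.114) than to their channel 2 (0.63, on which the genes were picked). A candidate explanation is that channel 2 of the OVA arrays holds the pool and channel 1 the single lungs. With the groups as labelled, goblet cell and type 2 genes would then be lower in OVA-labelled lungs. If the group names are exchanged as well, the deposited directions are those of challenged over PBS-treated lungs. These cases cannot be told apart, since there was no record of treatment besides the labels. Clca1 was at 0.362 in channel 1 of the OVA arrays and at 33.3 in channel 2 of the PBS arrays. A biological difference from the challenge itself stays open and untested.

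The second pattern is OVA replicate 2, where the skeletal muscle list had a median log2 ratio of -2.57 against -0.14 to 0.019 on the other 4 OVA arrays, from muscle genes high in channel 1 (Acta1 at 19.1, Myh8 at 40.1). Channel 2 of that array was raised for both genes as well, to a lesser degree. Acta1 was at 0.63 there against 0.24 to 0.26 on the other OVA arrays, and Myh8 at 2.83 against 0.45 to 0.69. Why both channels were raised was not tested. A noisier array is argued against, since its channel 1 deviated 0.847 times as much as the highest of the other 4. RNA of striated muscle in that lung piece may be a source, but only 46.2% of further muscle genes (6 of 13, of which Actn2 and Mb are in a fixed list too) were at least 2-fold above each other OVA array, which leaves it open. A squamous epithelium is open as well, with 55.6% (10 of 18, the most abundant being Krt13 at 40.7 against at most 0.06 and Lor at 39.1 against at most 0.40). No biological explanation was tested for this pattern.

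The third pattern is that alveolar type 1, endothelial and club cell lists fell with the preset correlation, while the alveolar type 2, ciliated and smooth muscle lists were not called; with an estimated correlation all 3 calls were lost (adjusted p = 0.077, 0.15 and 0.26). For compressed ratios of bright probes, 31 alveolar type 1 and endothelial genes brighter than the median tested alveolar type 2 gene (intensity 2.69) had a median of -0.54. This argues against compression only at the intensities of these genes. The cut rests on tested type 2 genes, so the brightest members, which may be missing, are not covered. A lower share of lung structural RNA in general would lower these lists alike. The median of the alveolar type 1 list differed from that of the ciliated list by -0.46 on the log2 scale (permutation p = 4e-05 over genes, which are not independent replicates). Taken per array, the difference was lower on the OVA arrays by 0.49 (exact p = 0.0079 over arrays, the smallest that 126 splits can give). The 2 lists were compared after their medians were seen, so both p-values restate the pattern. The PBS ratios also lie near 0, so lists that differ on the OVA arrays readily reach this smallest p. The comparison therefore does not decide on this cause. A difference between cell types that comes with the challenge stays open, in a direction that the first pattern leaves unsettled.

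The number of changed genes exceeded that of each other split tried: 1 of 100 splits, the labelled one, gave 10364 genes, and the highest other, which set OVA replicates 2 to 5 against the rest, gave 4833. The same held for changes of at least 2-fold (1 of 100, 782 against 491) and for lists with an estimated correlation (1 of 100, 8 against 0). For these 3 counts, 1 of 100 is the smallest share that 100 splits can give, so chance was not excluded. Each other split set OVA and PBS arrays in the same group, which adds their difference to the spread within groups. The sizes of the other counts therefore do not show what chance alone gives. For lists with the preset correlation, 8 of 100 splits gave at least 26, up to 29.

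Of 204 groups of values, 21 (10.3%) held an array that stood apart from the rest of its group, where chance gives about 5%, but in 9 of the 21 all other arrays of the group had the same value, as rounded intensities often give. Among genes these were Slc26a4 on OVA replicate 4 (log2 ratio 5.45), Saa3 and Tppp3 on OVA replicate 1 (3.12 and -0.62) and Tbxas1, thromboxane synthase, on OVA replicate 2 (2.41). On the PBS arrays they were Asgr1 and Itgax on replicate 3 (0.58 and -0.10), Cyp2a4 and Cyp2a5 on replicate 4 (-0.85 and -0.90), and Gpm6a, a mesothelial list member, on replicate 2 (-0.23). Among list medians they were T cell genes on OVA replicate 2 (0.41) and PBS replicate 3 (0.029), skeletal muscle genes on OVA replicate 2 (-2.57) and PBS replicate 4 (-0.022), adipose tissue genes on OVA replicate 4 (-1.27) and neutrophil genes on OVA replicate 5 (0.10). On the PBS arrays they were B cell, arginine and ribosomal protein genes on replicate 1 (0.0028, -0.013 and 0.017), NK cell and eicosanoid genes on replicate 2 (-0.078 and 0.0083) and xenobiotic metabolism genes on replicate 4 (-0.060). The authors' p-values per array, used in no comparison, were under 0.01 for at least 4081 probes on each OVA array and for at most 111 on each PBS array.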

How the results depend on the processing

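The OVA arrays alone against 0, 0.05 added to both channels, channel 1 alone and the turned ratios were chosen after seeing the data. The 10364 changed genes, the 782 changed at least 2-fold and the 26 shifted lists came out within 1.5 times with the second table, median centring, loess, the filter on dim probes, the mean over probes, each probe as its own test, array weights, a trended prior, the unmoderated test, an adjusted p under 0.01, 0.05 added and the OVA arrays alone, as far as each applies; 0.05 added lowered the fold of 12 named genes by over 1.5 times. Leaving out each array in turn gave 9143 to 10155 genes, 757 to 810 changed at least 2-fold and 24 to 26 lists. With the replicate number as a block there were 7661 genes, 787 changed at least 2-fold and 27 lists. Deviations of equally numbered arrays correlated at r from -0.35 to 0.091 over genes. Such correlations cannot show whether the numbers pair the lungs, and the labels do not state a pairing. Quantile normalised ratios gave 4528 genes (2180 higher, 2348 lower) and 447 changed at least 2-fold (360 higher, 87 lower), and 50 added to both channels left 1 gene at 2-fold, since it exceeds most intensities. A 2-fold threshold leaves 782 genes. With an estimated correlation 8 lists were called, and fry called 30, with the alveolar macrophage (adjusted p = 1.04e-06), neutrophil (0.00062), immediate early and stress (0.0013), sex-specific (0.015) and circadian clock (0.037) lists gained. With the ratios of the OVA arrays turned in sign, 10037 genes were called, and 9063 of the 9077 also called by the deposited ratio had the opposite sign. The PBS ratios lie near 0, so this reversal was fixed in advance. A block for slide or scan date was not run, since no such record was used.

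Channel 2 alone gave 0 genes (1638 at an unadjusted p under 0.05 with limma; 0 changed at least 2-fold) and 0 lists, so each call ended there; the other channel carries the difference. In this setting 33 named genes changed sign, with log2 changes of -0.082 for Il4ra, which had not passed the threshold, and, for 32 that had, Rnase2a -0.0049, Vmn1r75 -0.33, Chil4 -0.021, Fabp1 0.39, Pon1 0.16, Etv5 0.081, Esm1 0.21, Asgr1 0.0067, Cyp2a4 0.044, Cyp2a5 0.11, Il4 -0.024, Il5 -0.058, Il33 -0.048, Ccl24 -0.17, Ccl17 -0.028, Spdef -0.068, Chia1 -0.035, Arg1 -0.065, Ear2 -0.038, Ear12 -0.095, Batf3 -0.017, Itgax -0.051, Saa3 -0.12, Saa1 -0.0018, Timp1 -0.048, Gatm -0.12, Arg2 -0.055, Cav2 0.078, Gpm6a 0.050, Igfbp6 0.063, Sult1d1 0.19 and Mcpt8 -0.085. Among lists called by the ratio, the test of 15 changed direction, with medians of goblet cell and mucus 0.0079, eosinophil -0.020, B cell and plasma cell 0.022, mast cell and basophil -0.013, interferon-induced -0.012, extracellular matrix and remodelling -0.012, complement and acute phase -0.0019, club cell 0.0076, endothelial cell 0.012, xenobiotic metabolism 0.0083, cholesterol synthesis 0.0033, heart muscle 0.11, mesothelial -0.022, oxidative phosphorylation -0.043 and cytosolic ribosomal protein -0.032. Of the 65 named genes, 63 passed the threshold and 62 kept their side of it without each array, where a fit was possible. The exceptions were Nppb, called at a log2 change of 3.81 (adjusted p = 0.035) and kept only without PBS replicate 2 or OVA replicate 1 (adjusted p up to 0.098 without the others), also lost with quantile normalised ratios (0.34) and 50 added (0.35), Il4ra, which passed without PBS replicate 3 (0.0030), and Prg2, which passed without PBS replicate 2 (0.032). Both also passed with the filter on dim probes, a trended prior and the OVA arrays alone, and Il4ra with loess and array weights. Il5 was lost with the block (0.053) and with quantile normalised ratios (0.23). Heart muscle genes as a list were lost without PBS replicate 1 or 2 or OVA replicate 1 or 4 (adjusted p from 0.062 to 0.18), without dim probes (0.054) and by fry (0.079), and red blood cell genes without OVA replicate 1 (0.062) and without dim probes (0.068). With the block the circadian clock list was called (0.039). The cause was not tested. Low intensities limit the ratios of dim genes, and no signal over background was used.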

Other observations

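Further fixed lists moved with the deposited ratio, in directions that share the doubt about its sign. Of 33 eicosanoid pathway genes, 16 rose and 4 fell, also when adjusted over the list alone (median log2 change 0.21, camera adjusted p = 5.66e-05; with an estimated correlation, adjusted p = 0.033). The prostaglandin D2 receptor Ptgdr was 11.4-fold higher and Tbxas1 4.61-fold. Of 23 arginine and polyamine genes, 11 rose and 1 fell, also when adjusted over the list alone (median 0.17, adjusted p = 5.95e-04; with an estimated correlation, adjusted p = 0.033). Beside Arg1, Gatm, which makes the precursor of creatine, was 7.77-fold higher and Arg2, the mitochondrial arginase, 2.33-fold. Of 45 extracellular matrix genes, 21 rose and 7 fell, or 22 and 8 when adjusted over the list alone (median 0.16, adjusted p = 2.83e-04; with an estimated correlation, adjusted p = 0.26). They were led by Mmp12 at 44.6-fold, before the protease inhibitor Timp1 at 13.3-fold and osteopontin, Spp1, at 7.64-fold. With 0.05 added to both channels, chosen after seeing the data, the log2 change of Ptgdr went from 3.51 to 2.49 and that of Gatm from 2.96 to 2.34.

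The lists of T cells, of B and plasma cells and of mast cells and basophils were shifted upward with the preset correlation and by fry, but not with an estimated correlation. T cell genes rose in 21 and fell in 4 of 40 cases (median 0.24, adjusted p = 1.59e-05; with an estimated correlation, adjusted p = 0.17). B cell and plasma cell genes rose in 12 and fell in 1 of 28 (median 0.18, adjusted p = 0.012; with an estimated correlation, adjusted p = 0.48). Mast cell and basophil genes rose in 8 and fell in 2 of 18 (median 0.14, adjusted p = 0.012; with an estimated correlation, adjusted p = 0.077), with the cytokine Il6 at 6.81-fold and the basophil protease Mcpt8 at 4.12-fold. With 0.05 added to both channels, the log2 change of Il6 went from 2.77 to 2.13. The B cell call was lost with quantile normalised ratios (adjusted p = 0.056). For these 3 lists the counts were the same when adjusted over the list alone.

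The unfolded protein response list had 21 of 29 genes up and 3 down (median 0.31, adjusted p = 7.21e-08; with an estimated correlation, adjusted p = 0.071). Interferon-induced genes had 24 of 37 up and 3 down (median 0.42, adjusted p = 7.35e-07; with an estimated correlation, adjusted p = 0.31). Oxidative phosphorylation genes had 27 of 42 up and none down (median 0.21, adjusted p = 5.75e-07; with an estimated correlation, adjusted p = 0.26). Cytosolic ribosomal protein genes had 14 of 33 up and 2 down (median 0.076, adjusted p = 0.0069; with an estimated correlation, adjusted p = 0.15), and cholesterol synthesis genes 9 of 21 up and 2 down (median 0.12, adjusted p = 0.0069; with an estimated correlation, adjusted p = 0.28). Mesothelial genes had 9 of 16 down and 2 up (median -0.37, adjusted p = 0.016; with an estimated correlation, adjusted p = 0.11), with Gpm6a at -1.09 ± 0.08 SE and Igfbp6 at -0.90 ± 0.04. Red blood cell genes had 9 of 15 down and none up (median -0.37, adjusted p = 0.027; with an estimated correlation, adjusted p = 0.38; without OVA replicate 1, adjusted p = 0.062; without the dimmest 0.25 of probes, adjusted p = 0.068). The call of the ribosomal protein list was lost with quantile normalised ratios (adjusted p = 0.11). Adjusted over the list alone, the counts up and down were 21 and 3, 25 and 3, 28 and 1, 14 and 2, 10 and 2, 2 and 9, and 0 and 9, in the order given.

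With the preset correlation no shift was called for the lists of alveolar macrophages (8 up and 3 down of 22, adjusted p = 0.12, median -0.038 with a mean of 0.16), the circadian clock (3 up and 9 down of 19, adjusted p = 0.13), neutrophils (5 up and 3 down of 23, adjusted p = 0.26), immediate early and stress genes (11 up and 10 down of 35, adjusted p = 0.26, median -0.013 with a mean of 0.22) and sex-specific genes (1 up and 2 down of 9, adjusted p = 0.45). None was called for adipose tissue (0 past the threshold of 16, adjusted p = 0.45), lymph node stroma and thymus (3 up and 4 down of 15, adjusted p = 0.57), skeletal muscle (1 up and 0 down of 16, adjusted p = 0.58), smooth muscle (4 up and 4 down of 19, adjusted p = 0.84) or NK cells (2 up and 3 down of 15, adjusted p = 0.96). Adjusted over the list alone, the counts up and down were 8 and 3, 3 and 10, 5 and 3, 12 and 10, 1 and 2, 0 and 0, 3 and 4, 1 and 0, 4 and 4, and 2 and 3, in the order given.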
